A study of Mus musculus with 12 samples.

How the data were processed

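RNA-seq libraries were made by the submitters from sorted cardiac fibroblasts with the TruSeq Stranded mRNA kit, 3 from LepR-Cre+ and 3 from LepR-Cre− cells at each of P7 and P56. The submitters' processing notes name STAR 2.5.1b, edgeR and the mm10 genome build; the role of each in making the tables, the counting tool and whether counting used strand are not given in the sources used here. Per the file headers, the deposited tables hold normalized read counts, a signal in which each library's reads are divided by 1 scaling factor, and transcripts-per-million (TPM). The deposited TPM columns were made by the authors. The authors also deposited log2 fold changes of LepR-Cre+ over LepR-Cre− cells at P56 for their lists of genes. Beside these stand the authors' adjusted p-values (p-value column padj), for protein coding genes with a mean TPM of at least 1 in one population. In the P7 table every gene had a mean TPM of at least 1 in one population, which was checked on the values, while the P56 table was unfiltered. Each normalized column was a whole multiple of its smallest step, and whole reads were recovered by division by that step, with 100% of values within 0.01 read of a whole number.

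Groups and replicate numbers were taken from the labels. Coordinates are those of GENCODE M21 on GRCm38, in which 98.3% of the 32851 gene IDs of both tables together were found. Recovered reads ran from 22430064 to 34734645 per library. A 95% Wilson interval for the share of mitochondrial reads of a library reached at most 0.00681 percentage points to either side, and such intervals and the floor of 3 reads behind a count of 0 cover counting error only.

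The main test was limma 3.58.1 (R 4.3.3, eBayes with trend) on log2 of the normalized read count plus 0.5, for genes with a TPM of at least 1 in at least 3 of the libraries compared, with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold, with no threshold on fold. It was the test fixed for normalized values. The edgeR quasi-likelihood test had been fixed for raw counts, and was run with TMM scaling as an added alternative on the recovered reads. P7 and P56 were fitted separately, 6 libraries each. The change of the LepR-Cre difference with age was fitted as an interaction over the 12 libraries, with 4 group means, for the 15820 genes in both tables before the TPM filter. A difference in scaling between the tables cancels in that contrast. Comparisons of P7 with P56 within a population were not run, because the tables were normalized separately and age cannot be told apart from the table.

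The comparisons, the tests, 31 gene lists of pathways and cell types and the rule for named genes were fixed before the data were examined. The rule named Lepr and Col1a1, then the 8 higher and 8 lower genes with the largest absolute log2 fold change among genes that passed, had at least 10 CPM (reads scaled to the library total) in the higher group and had non-overlapping groups, without gene models named by number, mitochondrial or ribosomal protein genes. It then named up to 4 members with the smallest p of each list with a member that passed, and up to 6 genes in each direction for the interaction, where non-overlap was not required. Lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists tested, and again with the correlation estimated from the data and with fry. Camera compares a list with all other genes tested, whereas fry tests whether a list's genes move on balance in one direction. For each list the members passing were counted over all genes and adjusted over the list alone. Values of a few genes that the rule names are not reported here, while counts include them.

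Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, edgeR 4.0.16 with RLE scaling, other filters and pseudocounts, a fold threshold, the replicate number as a block, 1 fit of all 12 libraries and leaving out each library. Added after the values were seen were edgeR with TMM, limma on log2 TPM, leaving out gene models named Gm and a number, and library covariates (the share of mitochondrial reads, the percent of genes with a read and the level of the Y-linked gene Ddx3y), with further leave-one-out fits for the lists, the named genes and the authors' lists. No alternative for the authors' lists was fixed in advance. For the named genes only DESeq2, edgeR with RLE and the replicate block were. Each fit with a library left out used the genes of the full test. This was also chosen after the values were seen, since a first version applied the TPM filter again to the remaining libraries and so left genes expressed in the shortened group alone untested. The tests were tried on simulated data made from libraries of the same tables, in 5 runs with 200 genes changed. At 4-fold, limma recovered 74.2% of changed genes at P7, 80.9% at P56 and 47.3% for the interaction. At 2-fold it recovered 13.1%, 26.6% and 4.18%, and at 1.5-fold 1.19%, 2.39% and 0%. Of limma's calls 4.87%, 9.45% and 4.49% were false, against 26.8%, 24.4% and 26.7% of DESeq2's. In 5 simulated runs at P7, camera called the 1 list that had been moved in all 5 and 0 of 150 lists that had not. All simulated counts were drawn independently for each gene, and the simulated lists were random genes. These runs could therefore not test correlation between genes or differences that many genes of a library share. The false shares and the camera result hold only without them.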

Results

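Poly(A) RNA was sequenced from cardiac fibroblasts of CD1 mice that carried a Col1a1-GFP transgene, a Cre driver at the leptin receptor gene Lepr and a Cre-dependent tdTomato reporter. Cells positive for GFP were sorted by tdTomato into LepR-Cre+ and LepR-Cre− populations at postnatal day 7 (P7) and postnatal day 56 (P56). The 12 libraries formed 4 groups of 3. Recovered depth was 25526252 to 34734645 reads per library at P7, over 16316 genes, and 22430064 to 33264701 at P56, over 32355 genes. The P7 table held only genes with a mean of at least 1 TPM (transcripts-per-million, a length-scaled read count) in one of its populations, so genes below that level were not measured there. The labels do not say whether replicates came from separate animals, so each p-value measures only the spread between these samples. Values are means of normalized read counts ± SD with n = 3 per group, and fold changes are LepR-Cre+ over LepR-Cre− on the log2 scale, so a negative value is lower in LepR-Cre+ cells.

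The transcripts of Lepr and Col1a1 themselves, and not the GFP and tdTomato reporters used for sorting, were read first. Lepr, the leptin receptor gene (chromosome 4, 101717404 to 101815352, GRCm38), averaged 31793 ± 11807 in LepR-Cre+ and 11649 ± 3067 in LepR-Cre− libraries at P7, a log2 fold change of 1.42 (SE 0.31, adjusted p = 0.105), and was higher in all 3 LepR-Cre+ libraries than in any LepR-Cre− library. At P56 Lepr averaged 10368 ± 3199 against 5516 ± 2332, a log2 fold change of 0.97 (SE 0.36, adjusted p = 1.0), with overlapping groups. Col1a1, the type I collagen gene whose promoter drives the GFP transgene (chromosome 11, 94936224 to 94953042), had a log2 fold change of 0.61 at P7 (SE 0.21, adjusted p = 0.351) and 0.39 at P56 (SE 0.25, adjusted p = 1.0). Neither gene passed limma at either age. On simulated data that test recovered only 26.6% of 2-fold changes at P56, so a miss there does not show that a difference is absent. The authors' deposited list holds Lepr as higher at P56, with a log2 fold change of 0.97. Their adjusted p was 1.76e-08, by a test not given in the sources used here. With the replicate number as a block, for which the labels give no ground, Lepr passed at P7 (adjusted p = 0.00148) and P56 (adjusted p = 0.0336). At P7, sex-linked transcripts argue against libraries from the same animals for replicates 1 and 3, but cannot bear on other links by number. At P56 they matched by number. DESeq2 passed Lepr (adjusted p = 0.000855) and Col1a1 (adjusted p = 0.0432) at P7. Lepr transcripts were abundant in both populations.

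The P7 comparison asked how LepR-Cre+ fibroblasts, which the series title calls adventitial, differed from the LepR-Cre− fibroblasts that it calls interstitial. Of 14825 genes tested, 148 passed at an adjusted p under 0.05, with 106 higher and 42 lower in LepR-Cre+ cells. That balance depends on the test, with 336 and 292 in DESeq2, 238 and 197 with the replicate number as a block, and 65 and 12 with the Ddx3y level as a covariate. The largest rise among the genes named by rule was in Hhip, a secreted hedgehog antagonist (chromosome 8, 79965851 to 80058006), from 6.03 ± 7.32 to 374 ± 135, a log2 fold change of 6.81 (SE 1.11). With 0 reads in LepR-Cre− replicate 2 that value depends on the pseudocount: Hhip had 7.64 (adjusted p = 0.102) with 0.1 in place of 0.5, 5.90 (adjusted p = 0.0171) in edgeR with TMM, and 1.99 (adjusted p = 0.116) on log2 TPM. Foxd1, a forkhead transcription factor, rose by 5.42 (SE 0.43), Esm1, which encodes the proteoglycan endocan, by 5.39 (SE 0.32), and Tspan11, a tetraspanin gene (chromosome 6, 127887589 to 127953977), by 5.06 (SE 0.32). Tspan11 went from 177 ± 70.6 to 5540 ± 508. Further rises were those of Sfrp4, a secreted Wnt modulator, at 4.56 (SE 0.36), Gdf10, a member of the TGF-beta superfamily, at 4.55 (SE 0.20, from 526 ± 117 to 12223 ± 1883), Agtr2, the angiotensin II type-2 receptor gene, at 4.17 (SE 0.23), and Ccn4, a matricellular protein gene, at 4.02 (SE 0.23).

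The 8 lower genes named by rule at P7 were led by Actg2, the enteric smooth muscle actin gene, which went from 548 ± 44.0 to 95.5 ± 53.9, a log2 fold change of -2.71 (SE 0.46). Matn4, a matrilin gene of the extracellular matrix, had -2.22 (SE 0.36), Tinagl1 -1.96 (SE 0.29), Cnn1, the smooth muscle calponin gene, -1.85 (SE 0.31), and Efemp1, which encodes fibulin-3, -1.81 (SE 0.27). Max, the dimerisation partner of Myc, had -1.76 (SE 0.23), Nt5e, the gene of the ecto-nucleotidase CD73, -1.72 (SE 0.24), and Diras2 -1.59 (SE 0.24). Adjusted p across these 16 genes ran from 0.000329 for Gdf10 to 0.0450 for Actg2, and each had 3 libraries of one group above the 3 of the other. Non-overlapping groups were found for all 148 genes that passed, and for 17.2% of all genes tested, where chance gives 10%.

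The count at P7 rested on single libraries. It was 35 without LepR-Cre− replicate 1, 49 without LepR-Cre− replicate 3, 29 without LepR-Cre+ replicate 1 and 112, 113 and 107 without LepR-Cre− replicate 2, LepR-Cre+ replicate 2 and LepR-Cre+ replicate 3, and no gene passed as lower in the fits without LepR-Cre− replicate 1, LepR-Cre− replicate 3 or LepR-Cre+ replicate 1. Of the 16 genes above, Foxd1, Esm1, Tspan11, Sfrp4, Gdf10, Agtr2 and Ccn4 passed in every fit with a library left out. Hhip missed the threshold without LepR-Cre− replicate 1 (adjusted p = 0.180), LepR-Cre+ replicate 1 (adjusted p = 0.182), LepR-Cre+ replicate 2 (adjusted p = 0.0809) or LepR-Cre+ replicate 3 (adjusted p = 0.105). Each of the 8 lower genes missed it in at least 3 of those fits. All 8 missed it without LepR-Cre− replicate 1 (adjusted p from 0.0769 for Max to 0.249 for Cnn1), LepR-Cre− replicate 3 (adjusted p from 0.0940 for Max to 0.177 for Actg2) or LepR-Cre+ replicate 1 (adjusted p from 0.0510 for Matn4 to 0.136 for Diras2).

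**Figure D1:**
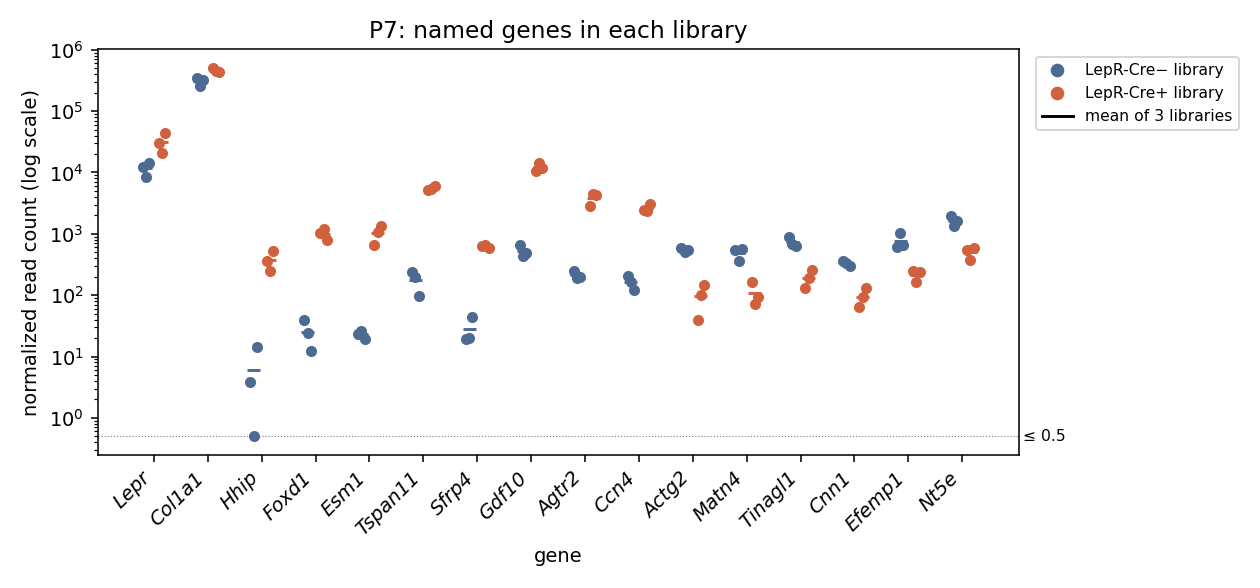
Normalized read counts (log scale) of Lepr, Col1a1 and 14 of the genes named by rule in each P7 library; points are libraries, short bars are means of 3, and values at or below 0.5 are drawn on the dotted line. Tspan11 averaged 177 in LepR-Cre− and 5540 in LepR-Cre+ libraries, and the LepR-Cre+ points of Actg2 all lie below its LepR-Cre− points.

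In the hedgehog list at P7, 3 of 11 measured members rose, 0 fell and 8 did not pass. Hhip and the transcriptional effector Gli1, at 2.10 (SE 0.26), were among those that rose, while the co-receptor gene Boc had 2.15 (SE 0.37, adjusted p = 0.0514). Adjusted over the list alone, 5 rose and 1 fell. The list as a whole passed in the upward direction (camera, median 0.07, adjusted p = 0.0247), with adjusted p = 0.729 with an estimated correlation, and adjusted p = 0.138 without LepR-Cre− replicate 2 and 0.236 without LepR-Cre+ replicate 3. On log2 TPM the hedgehog list did not pass. Of 19 Wnt genes, 3 rose, 1 fell and 15 did not pass: Sfrp4, the ligand gene Wnt2 at 3.59 (SE 0.38) and the secreted antagonist gene Sfrp1 at 1.10 (SE 0.14) rose, and Wnt10b fell to 11.3 ± 2.54 from 70.1 ± 7.65 (log2 fold change -2.60, SE 0.37). Adjusted over the list alone, 6 Wnt genes rose and 3 fell, and the list did not pass (adjusted p = 0.0836). Of 29 TGF-beta and BMP genes, 3 rose (Gdf10, Tgfbi at 2.93 and Bmp3 at 4.01), 1 fell (Bmper, a BMP-binding regulator, at -1.58) and 25 did not pass, with 4 up and 5 down adjusted over the list alone. That list did not pass (adjusted p = 0.317), with a median of -0.28 and a downward test beside a mean of 0.03. Gli1 missed the threshold without LepR-Cre− replicate 3 (adjusted p = 0.0608) or LepR-Cre+ replicate 1 (adjusted p = 0.0946). Sfrp1 missed it without LepR-Cre− replicate 1 (adjusted p = 0.0990), LepR-Cre− replicate 3 (adjusted p = 0.0788) or LepR-Cre+ replicate 1 (adjusted p = 0.105), and Bmper without LepR-Cre− replicate 1 (adjusted p = 0.0876), LepR-Cre− replicate 3 (adjusted p = 0.0665) or LepR-Cre+ replicate 1 (adjusted p = 0.0777). Wnt10b missed it without LepR-Cre− replicate 1 (adjusted p = 0.177), LepR-Cre− replicate 2 (adjusted p = 0.0709), LepR-Cre− replicate 3 (adjusted p = 0.153) or LepR-Cre+ replicate 1 (adjusted p = 0.101). Without LepR-Cre+ replicate 1, Wnt2 (adjusted p = 0.0656) and Bmp3 (adjusted p = 0.0519) missed it too.

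Among growth factors of vessels, 3 of 25 members rose at P7 and 0 fell: Esm1, the fibroblast growth factor gene Fgf7 at 2.55 (SE 0.23) and Igf1 at 1.24 (SE 0.16). Adjusted over the list alone, 6 rose and 3 fell, and the list did not pass (adjusted p = 0.317). In the complement list Colec12 rose by 0.77 (SE 0.13), with 11 of 13 members not passing and 4 up and 2 down adjusted over the list alone (camera adjusted p = 0.160). The alarmin gene Il33 rose by 3.73 (SE 0.18, from 172 ± 19 to 2293 ± 300) and was the only 1 of 17 chemokine and cytokine genes to pass, with 5 up and 5 down adjusted over the list alone (camera adjusted p = 0.598). Dio2, the type 2 deiodinase gene, rose by 3.51 (SE 0.35) as the only 1 of 20 leptin and adipogenic genes, against 2 up and 0 down adjusted over the list alone (camera adjusted p = 0.160). Those 2 were Dio2 and Lepr, the gene of the Cre driver used for sorting. Nrp1, a semaphorin and VEGF co-receptor gene, rose by 1.41 (SE 0.19) as the only 1 of 19 axon guidance genes, against 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.291). Foxd1 and Twist2, at 1.28 (SE 0.19), rose among 21 developmental transcription factors, against 4 up and 5 down adjusted over the list alone (camera downward, adjusted p = 0.480, median -0.15, mean 0.10). Without LepR-Cre+ replicate 1, adjusted p was 0.111 for Igf1, 0.0519 for Dio2 and 0.0878 for Nrp1. It was 0.111 for Igf1, 0.0543 for Dio2 and 0.0927 for Nrp1 without LepR-Cre− replicate 1. It was 0.0950 for Igf1 and 0.0716 for Nrp1 without LepR-Cre− replicate 3, and 0.0507 for Igf1 without LepR-Cre+ replicate 3. Colec12 (adjusted p from 0.0841 to 0.211) and Twist2 (0.0670 to 0.146) missed the threshold whichever of the 6 libraries was left out.

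Matrix genes at P7 split. Of 19 basement membrane genes, 2 rose: Col4a4 at 2.95 (SE 0.32) and Col4a3 at 2.31 (SE 0.38), neighbouring collagen IV genes that share a promoter region. Adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.480). Of 22 elastic fibre genes, Fbln5, which encodes fibulin-5, rose by 1.45 (SE 0.15, from 10979 ± 1427 to 29979 ± 2631), Efemp1 and Emilin2 (-1.21, SE 0.18) fell, and 19 did not pass, with 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.480). Fibrillar collagens and collagen assembly genes had a median of 0.26 over 30 members with 0 passing and 3 up and 0 down adjusted over the list alone. Their list passed upward (adjusted p = 0.0247, and adjusted p = 0.729 with an estimated correlation) but not without LepR-Cre− replicate 2 (adjusted p = 0.173) or LepR-Cre+ replicate 3 (adjusted p = 0.385). On log2 TPM the collagen list did not pass. In the myofibroblast list Ddah1, a dimethylarginine hydrolase gene, rose by 1.93 (SE 0.18) and Cnn1 fell, with 17 of 19 not passing, 4 up and 7 down adjusted over the list alone, and a camera adjusted p of 0.317. Col4a3 missed the threshold without LepR-Cre− replicate 1 (adjusted p = 0.202), LepR-Cre− replicate 2 (adjusted p = 0.0665), LepR-Cre− replicate 3 (adjusted p = 0.147) or LepR-Cre+ replicate 1 (adjusted p = 0.163), and Col4a4 without LepR-Cre+ replicate 1 (adjusted p = 0.0510). Fbln5 missed it without LepR-Cre− replicate 1 (adjusted p = 0.0651) or LepR-Cre+ replicate 1 (adjusted p = 0.0510). Emilin2 missed it without any 1 library other than LepR-Cre+ replicate 3 (adjusted p from 0.0594 to 0.186). Efemp1 missed it whichever of the 6 was left out (adjusted p from 0.0572 to 0.112).

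Of the lists of other cell types, smooth muscle, mesothelial and cardiomyocyte markers passed downward at P7 with the preset correlation alone. Of 8 smooth muscle markers, Actg2, Cnn1 and Des (-1.09, SE 0.18) fell and 5 did not pass, with 7 down and 0 up adjusted over the list alone. That list passed downward (median -1.08, adjusted p = 4.69e-08), with adjusted p = 0.462 with an estimated correlation. Des missed the threshold whichever of the 6 libraries was left out (adjusted p from 0.0622 to 0.228). Actg2 and Cnn1 missed it without any 1 library other than LepR-Cre+ replicate 3 (adjusted p from 0.0519 to 0.249). Of 8 mesothelial and epicardial markers, Upk1b fell, from 85.7 ± 7.51 to 2.29 ± 3.96 (log2 fold change -6.13, SE 1.04), and 7 did not pass, among them Upk3b at 14.7 ± 13.9 against 220 ± 15.7 (adjusted p = 0.183), with 5 down adjusted over the list alone. This list passed downward (median -1.27, adjusted p = 0.000208), with adjusted p = 0.342 with an estimated correlation. With 0 reads in 2 of 3 LepR-Cre+ libraries, Upk1b had -7.70 at a pseudocount of 0.1 (adjusted p = 0.0940), -5.07 in edgeR with TMM (adjusted p = 0.0619) and -1.68 on log2 TPM (adjusted p = 0.157). Upk1b also missed the threshold without any 1 library other than LepR-Cre+ replicate 3 (adjusted p from 0.0940 to 0.220). Cardiomyocyte markers had a median of -0.51 over 14 members with 0 passing, over all genes and adjusted over the list alone. Their list passed downward (adjusted p = 0.00930, and adjusted p = 0.729 with an estimated correlation) but not without LepR-Cre− replicate 3 (adjusted p = 0.0730) or LepR-Cre+ replicate 3 (adjusted p = 0.236). Endothelial, pericyte, myeloid, lymphocyte and erythroid markers, matrix proteases, and proliferation and interferon genes had 0 members passing at P7, over all genes and adjusted over the list alone, and none of these lists passed (adjusted p from 0.160 to 0.733).

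The adventitial fibroblast list was also lower in LepR-Cre+ cells at P7. Of 18 measured members 1 fell, Efhd1 at -1.24 (SE 0.18), 0 rose and 17 did not pass, with 8 down and 0 up adjusted over the list alone. Efhd1 missed the threshold without any 1 library other than LepR-Cre+ replicate 2 (adjusted p from 0.0635 to 0.173). Pi16, a marker of adventitial fibroblasts, had 4132 ± 642 against 9905 ± 3508 (log2 fold change -1.22, adjusted p = 0.0876) and Dpp4, which encodes a surface peptidase, -1.20 (adjusted p = 0.109). The list passed downward (median -0.59, adjusted p = 9.22e-08) in every fit with a library left out, with adjusted p = 0.342 with an estimated correlation. Interstitial fibroblast markers had a median of 0.01 over 12 members with 0 passing, 1 up and 0 down adjusted over the list alone, and a camera adjusted p of 0.395. Immediate early and heat shock genes had a median of -0.19 over 27 members with 0 passing and 4 down adjusted over the list alone. That list passed downward (adjusted p = 0.00343, and adjusted p = 0.729 with an estimated correlation) but not without LepR-Cre− replicate 2 (adjusted p = 0.173) or LepR-Cre+ replicate 1 (adjusted p = 0.118).

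At P56 the same question was asked of adult cells. Of 14830 genes tested, 3 passed, all with non-overlapping groups, against 467 at an unadjusted p under 0.05. Tspan11 rose from 31.6 ± 14.5 to 460 ± 72.7, a log2 fold change of 3.92 (SE 0.34, adjusted p = 0.0264). Wif1, which encodes a secreted Wnt inhibitor (chromosome 10, 121033960 to 121100650), fell from 1858 ± 1220 to 53.5 ± 21.4, a log2 fold change of -5.0 (SE 0.48, adjusted p = 0.0288). Gm10800, a predicted gene model (chromosome 2, 98666547 to 98667301) that the rule for named genes leaves out and that is named here after its values were seen, rose from 40.4 ± 19.9 to 1790 ± 999.5, a log2 fold change of 5.38 (SE 0.58, adjusted p = 0.0493).

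Several genes with non-overlapping groups at P56 came near the threshold and did not pass. Among them, chosen after their values were seen, Esm1 had 117 ± 53.9 against 6.20 ± 2.74 (log2 fold change 4.12, SE 0.49, adjusted p = 0.0667), Prss35, a serine protease gene, 8.84 ± 5.24 against 242 ± 96.9 (-4.82, SE 0.58, adjusted p = 0.0667) and Kcne4, a potassium channel subunit gene, 1.36 (SE 0.18, adjusted p = 0.0734). Gdf10 had 2554 ± 868 against 354 ± 329 (log2 fold change 3.20, SE 0.58, adjusted p = 0.263). Non-overlapping groups were found for 6.88% of all genes tested, where chance gives 10%. The limma count of 3 became 0 without LepR-Cre− replicate 2 (950 at an unadjusted p under 0.05), LepR-Cre− replicate 3 (393), LepR-Cre+ replicate 2 (381) or LepR-Cre+ replicate 3 (338), and 5 without LepR-Cre− replicate 1 and 4 without LepR-Cre+ replicate 1. Limma-voom passed 0 genes (461 at an unadjusted p under 0.05), edgeR with TMM 1, DESeq2 85 and limma with the replicate number as a block 27. Tspan11, Wif1 and Gm10800 each missed the threshold in the 4 leave-one-out fits with a count of 0. In the order given above, adjusted p was 0.107, 0.116, 0.127 and 0.111 for Tspan11, 0.121, 0.105, 0.127 and 0.111 for Wif1, and 0.121, 0.254, 0.151 and 0.306 for Gm10800.

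**Figure D2:**
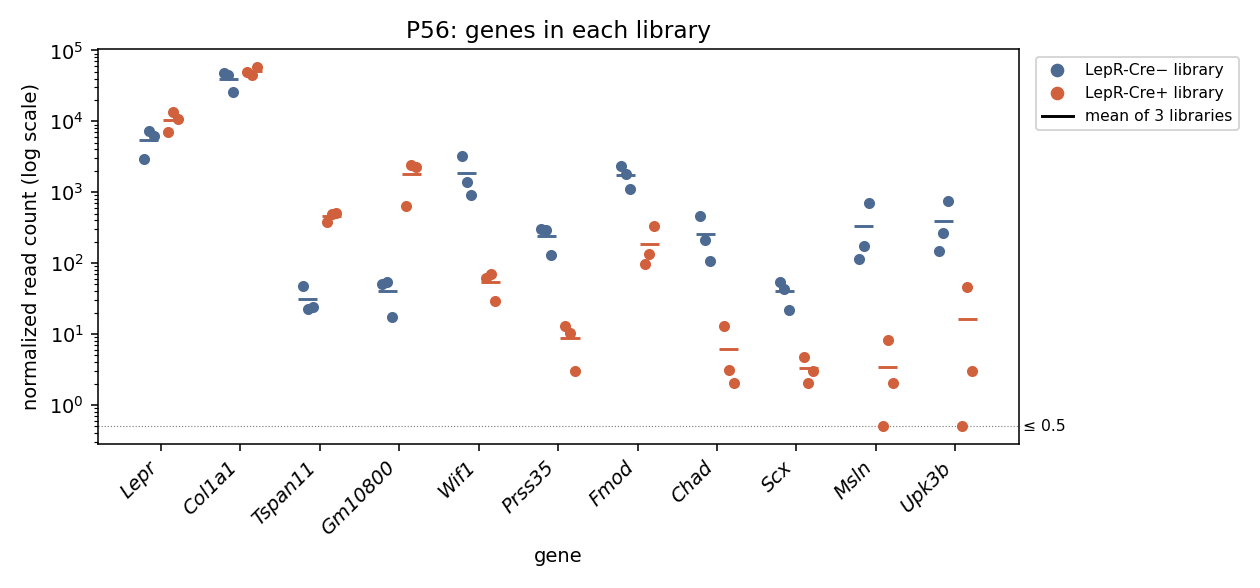
Normalized read counts (log scale) of 11 genes in each P56 library; points are libraries, short bars are means of 3, and values at or below 0.5 are drawn on the dotted line. Tspan11, Gm10800 and Wif1 passed the test, and Prss35, Fmod, Chad, Scx, Msln and Upk3b have every LepR-Cre− library above every LepR-Cre+ library without passing.

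At P56 the valve interstitial and tendon-like list passed downward with the preset correlation alone. Of 13 valve interstitial and tendon-like markers, 1 fell (Wif1), 0 rose and 12 did not pass, with 6 down and 2 up adjusted over the list alone. Fmod, the gene of the collagen-binding proteoglycan fibromodulin, had 187 ± 125 against 1758 ± 614 (log2 fold change -3.37, adjusted p = 0.0734). Chad, the chondroadherin gene, had 6.09 ± 6.15 against 260 ± 184 (adjusted p = 0.0768) and Scx, the tendon transcription factor gene scleraxis, 3.29 ± 1.38 against 39.96 ± 16.7 (adjusted p = 0.153), while Cilp, a cartilage matrix protein gene, had a positive log2 fold change of 1.2 (adjusted p = 0.396). The list passed downward (median -0.52, adjusted p = 1.41e-09), with adjusted p = 0.10 with an estimated correlation. Of 16 myofibroblast and matrifibrocyte genes, 0 passed, with 7 down and 1 up adjusted over the list alone. That list passed downward (median -0.61, adjusted p = 3.62e-10), with adjusted p = 0.0574 with an estimated correlation and adjusted p = 0.0437 by fry. Fmod, Chad, Scx and Cilp are among the members that both lists hold, so the calls are not independent.

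Mesothelial and epicardial markers formed the list with the lowest median at P56, -4.58 over 9 members, with 0 passing and 5 down adjusted over the list alone. Msln, the mesothelin gene (chromosome 17, 25748613 to 25754378), had 3.43 ± 4.31 against 333 ± 325 (log2 fold change -6.78, SE 1.04, adjusted p = 0.122), with 0 reads in LepR-Cre+ replicate 1, so its fold depends on the pseudocount. Upk3b, a uroplakin gene, had 16.2 ± 25.4 against 387 ± 318 (adjusted p = 0.472). The list passed downward (adjusted p = 3.62e-10, and adjusted p = 0.10 with an estimated correlation) in every fit with a library left out. LepR-Cre− replicate 3 held the highest level of 8 of the 9 members among LepR-Cre− libraries, with 707 normalized reads of Msln and 748 of Upk3b. The 19 adventitial fibroblast markers had a median of -0.26 with 0 passing and 2 down adjusted over the list alone. They passed downward as a list (adjusted p = 1.45e-06, and adjusted p = 0.10 with an estimated correlation) in every fit with a library left out.

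Hedgehog genes were higher as a list at P56, with a median of 0.38 over 10 members, 0 passing and 2 up adjusted over the list alone (adjusted p = 0.000361, and adjusted p = 0.379 with an estimated correlation). Gli1 had 292 ± 111 against 95.2 ± 24.3 (log2 fold change 1.57, adjusted p = 0.384) and Boc 1970 ± 45.6 against 1137 ± 221 (0.81, adjusted p = 0.374), each with non-overlapping groups. In the Wnt list Wif1 fell and 16 of 17 did not pass, among them Dkk3 at -1.02 (adjusted p = 0.640), with 2 down adjusted over the list alone. The Wnt list did not pass (adjusted p = 0.336), and its median of 0.02 and mean of -0.28 differed in sign. Myeloid markers had a median of 0.53 over 9 members with 0 passing (list adjusted p = 0.00208, and adjusted p = 0.452 with an estimated correlation), and lost the call without LepR-Cre− replicate 2 (adjusted p = 0.215) or LepR-Cre+ replicate 1 (adjusted p = 0.444).

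The remaining lists that passed at P56 were lower in LepR-Cre+ libraries, with 0 members passing over all genes. Endothelial markers had a median of -0.62 over 8 members (adjusted p = 0.000831, and adjusted p = 0.452 with an estimated correlation) and missed the threshold without LepR-Cre− replicate 2 (adjusted p = 0.303) or LepR-Cre+ replicate 1 (adjusted p = 0.161). Smooth muscle markers had -0.30 over 6 members (adjusted p = 0.00296, and adjusted p = 0.15 with an estimated correlation) and missed it without LepR-Cre− replicate 2 (adjusted p = 0.0748) or LepR-Cre+ replicate 1 (adjusted p = 0.0987). Cardiomyocyte markers had -0.33 over 10 members (adjusted p = 0.00582, and adjusted p = 0.452 with an estimated correlation), with 1 down adjusted over the list alone. That gene, the atrial myosin light chain gene Myl7, had 48.9 ± 57.3 normalized reads in LepR-Cre− libraries and 0 reads in each LepR-Cre+ library, at least 15.1-fold lower with 0 set to 3 reads per library. With Myl7 at that bound the list's median was again -0.33. LepR-Cre− replicate 3 had 115 normalized reads of Myl7, and without that library the bound was 4.94-fold. The cardiomyocyte call was lost without LepR-Cre− replicate 2 (adjusted p = 0.0645), LepR-Cre− replicate 3 (adjusted p = 0.494) or LepR-Cre+ replicate 1 (adjusted p = 0.553). Interferon response genes had -0.11 over 25 members (adjusted p = 0.00783, and adjusted p = 0.452 with an estimated correlation) and missed the threshold without LepR-Cre− replicate 3 (adjusted p = 0.780) or LepR-Cre+ replicate 1 (adjusted p = 0.177). Erythroid markers had -0.35 over 5 members (adjusted p = 0.0180, and adjusted p = 0.452 with an estimated correlation) and missed it without LepR-Cre− replicate 1 (adjusted p = 0.333), LepR-Cre− replicate 2 (adjusted p = 0.0645), LepR-Cre+ replicate 1 (adjusted p = 0.406) or LepR-Cre+ replicate 3 (adjusted p = 0.0582). Apart from Myl7, 0 members of these lists and of the myeloid list were down or up adjusted over the list alone.

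**Figure D3:**
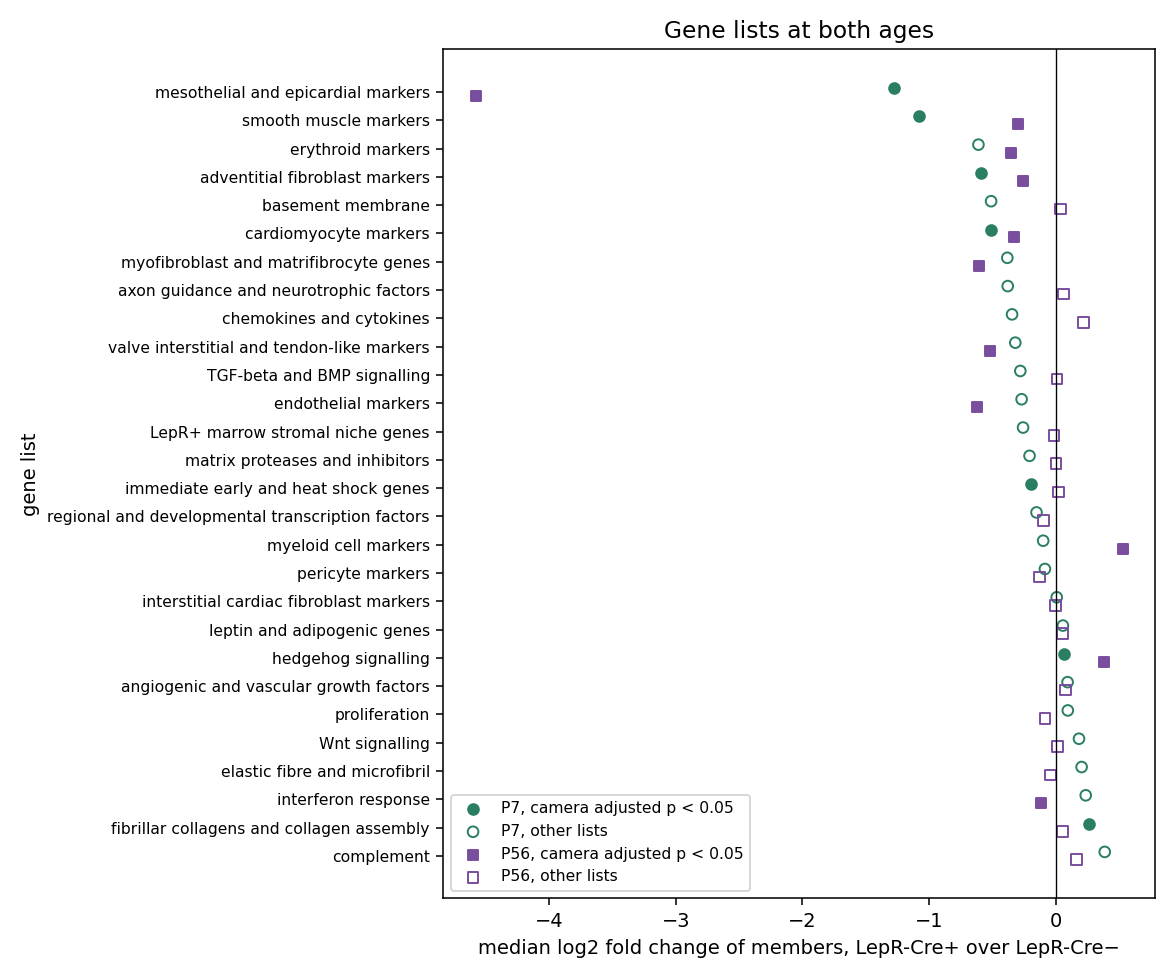
Median log2 fold change of the measured members of each gene list, LepR-Cre+ over LepR-Cre−, at P7 (circles) and P56 (squares); filled points passed camera with its preset correlation. Mesothelial and epicardial markers have the lowest median at both ages, -1.27 at P7 and -4.58 at P56, and 0 lists passed camera at either age with an estimated correlation.

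Whether the LepR-Cre difference changed with age was tested as the P56 difference minus the P7 difference in 1 fit of all 12 libraries. Of 15528 genes tested, 19 passed, all with a lower value at P56, against 1103 at an unadjusted p under 0.05. The balance depends on the test, with 39 higher and 98 lower in DESeq2 and 22 and 65 with the replicate number as a block. Without P7 LepR-Cre+ replicate 3 it was 4 and 15. Genes with a mean under 1 TPM in both P7 populations are outside the P7 table. A difference that arose only at P56 in such a gene could not be tested. Prss35 (chromosome 9, 86743649 to 86758443) had a difference of differences of -5.85 (SE 0.69, adjusted p = 0.00464), from 1.03 (SE 0.49) at P7 to -4.82 (SE 0.49) at P56. Its P56 difference did not pass limma in the P56 libraries alone, so a reversal of direction is not shown. Sfrp4 had -3.92 (SE 0.56), Rbp4, a retinol transport protein gene, -3.29 (SE 0.37), Il33 -3.08 (SE 0.45), Itgbl1 -3.00 (SE 0.30) and Enpep, the gene of the angiotensin-cleaving aminopeptidase A, -2.71 (SE 0.37). In LepR-Cre− cells the mean TPM of Il33 was 1.84 ± 0.15 at P7 and 41.8 ± 19.99 at P56, and that of Rbp4 was 2.48 ± 0.52 and 38.03 ± 11, values from separately made tables that were not tested against each other.

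Of the lists fixed, myofibroblast and matrifibrocyte genes (mean -0.71, adjusted p = 0.00567) and valve interstitial and tendon-like markers (mean -0.72, adjusted p = 0.0220) passed downward for the difference between ages, with 0 members passing in either, and both had adjusted p = 0.505 with an estimated correlation. Without P7 LepR-Cre− replicate 2 both calls were lost (adjusted p = 0.103), as they were without P7 LepR-Cre+ replicate 3 (adjusted p = 0.0653). The valve list also missed the threshold without P56 LepR-Cre− replicate 1 (adjusted p = 0.0607) or P56 LepR-Cre− replicate 2 (adjusted p = 0.0503). The gene count was 10 without P7 LepR-Cre− replicate 1, 8 without P7 LepR-Cre− replicate 3, 8 without P7 LepR-Cre+ replicate 1, 11 without P56 LepR-Cre− replicate 1, 8 without P56 LepR-Cre− replicate 3 and 10 without P56 LepR-Cre+ replicate 2. Prss35, Rbp4, Itgbl1 and Enpep passed in each of the 12 fits with a library left out, but on log2 TPM Itgbl1 had -1.49 (adjusted p = 0.228). Sfrp4 missed the threshold in 4 of them and Il33 in 6, with adjusted p up to 0.0658 and 0.0743.

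**Figure D4:**
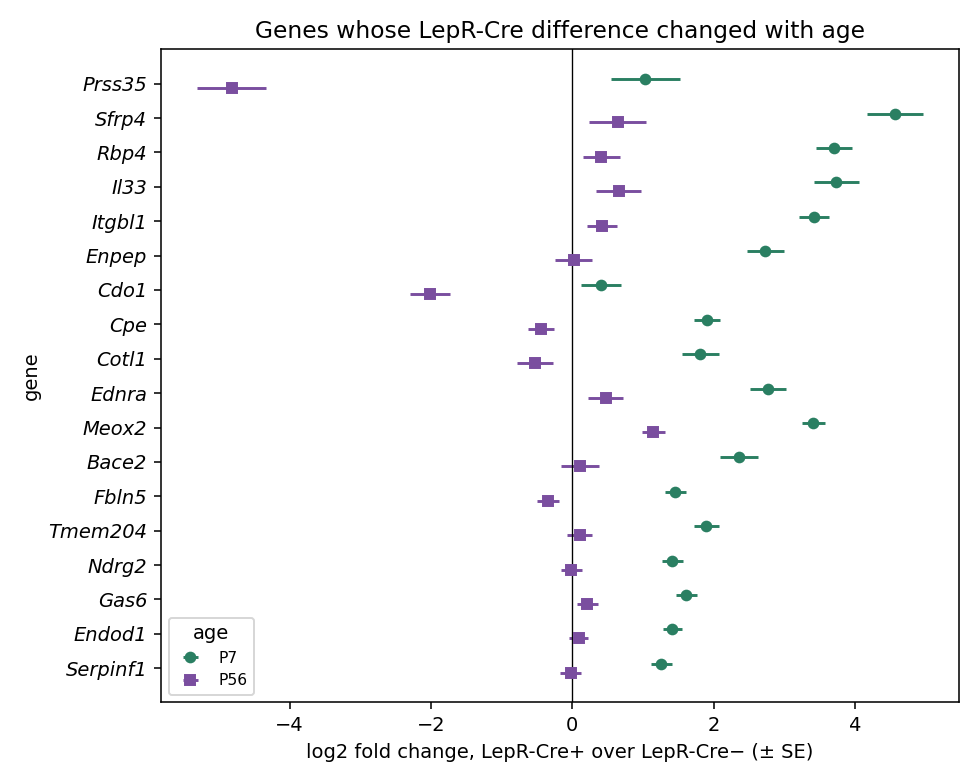
Log2 fold change of LepR-Cre+ over LepR-Cre− at P7 (circles) and P56 (squares) with its SE, for 18 of the 19 genes whose difference changed with age in the fit of 12 libraries. Each gene drawn lies lower at P56, as for Sfrp4 at 4.56 and 0.64. Prss35 is among those whose values differ in sign, at 1.03 (SE 0.49) and -4.82 (SE 0.49), which alone does not show a reversal.

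Over the 13149 genes tested at both ages, Tspan11 was the 1 gene that passed at both. Log2 fold changes at P7 and P56 had a Pearson correlation of 0.0845 and a Spearman correlation of -0.0382 across genes, which are not independent replicates, and 46.0% of genes had the same sign at both ages.

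The authors deposited lists of 39 genes higher and 67 genes lower in LepR-Cre+ cells at P56, chosen on these samples, so they are not independent evidence of direction. Of the higher list 38 genes were tested here, all 38 had the authors' sign and 2 passed (Tspan11 and Gm10800). Of the lower list 60 were tested, all 60 had the authors' sign and 1 passed (Wif1). The log2 fold changes of the authors' deposited table and those fitted here had a Pearson correlation of 0.997 across these genes. Every listed gene had an adjusted p of at most 0.0497 in the authors' own test, and DESeq2 passed 51 of them here. The low count with limma thus goes with the test and not with other fold changes. At P7, 33 genes of the higher list were tested, 31 had the same sign and 18 passed in that direction, while of the lower list 55 were tested, 45 had the same sign and 8 passed in that direction, with 1 passing in the opposite one. Among the authors' higher genes were Foxd1, Esm1, Gdf10, Gli1, Boc and Lepr, each with a positive value at both ages where it was tested here.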

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

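Tests chosen after the result was seen are those of depth, of Gm10800 at P7, of the share of fibroblasts, of mesothelial and of valve or tendon-like cells, and of the size of the differences at P56. A difference between ages, by a test of the difference itself, singled out 7 genes and 2 lists named in the text. On the log2 scale, the LepR-Cre difference at P56 minus that at P7 was -5.85 for Prss35, -3.92 for Sfrp4, -3.29 for Rbp4, -3.08 for Il33, -3.00 for Itgbl1, -2.71 for Enpep and -1.80 for Fbln5. Mean differences were -0.71 for myofibroblast and matrifibrocyte genes and -0.72 for valve interstitial and tendon-like markers, and both lists had adjusted p = 0.505 with an estimated correlation.

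Chance can be excluded for neither interaction count. Of 100 splits of the libraries within each age, the real one included, 13 gave at least 19 genes (highest other 463) and 92 gave at least 2 lists (highest other 12). Each of the 13 splits kept the real P7 grouping or used the P7 split with 737 genes described below. With the real P7 grouping, splits at P56 other than the real one gave up to 71 genes. A count of 19 can thus arise without the real P56 grouping. Such splits still hold the real P7 difference, so the splits are not a clean measure of chance for the interaction. With 10 splits of 6 libraries at each age, a share under 0.05 cannot be reached. At P7, 2 of the 10 gave at least 148 genes, and the other count was 737; 4 gave at least 7 lists, with 12 as the highest other. At P56, 2 gave at least 3 genes, with 515 as the highest other, and 1 gave at least 11 lists, with 9 as the highest other.

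Both large counts point to a structure of the samples apart from the sorted populations. The split with 737 genes at P7 set LepR-Cre− replicates 1 and 3 and LepR-Cre+ replicate 3, with 0.508 to 0.797% mitochondrial reads, against the remaining libraries, with 0.212 to 0.273%. With the log2 mitochondrial share as a covariate, 432 genes passed at P7. The split with 515 genes at P56 set LepR-Cre− replicates 1 and 3 and LepR-Cre+ replicate 1, in which 67.5 to 70.4% of genes had a read, against the remaining libraries, with 74.3 to 89.6%. With that percentage as a covariate, 5 genes passed at P56.

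Of 3 repeat-type gene models looked at after their values were seen, Gm10800 passed at P56 (adjusted p = 0.0493), but not in edgeR with TMM (adjusted p = 0.0810), limma-voom (adjusted p = 0.447) or 4 of 6 leave-one-out fits, and Gm10801 (adjusted p = 0.0734) and Gm10717 (adjusted p = 0.109) did not pass. Gm10800 had 638, 2431 and 2300 normalized reads against 50.1, 53.5 and 17.6, and the higher list of the authors' deposited table also holds Gm10801 and Gm10717. Greater depth is argued against, since LepR-Cre+ libraries had 0.822 times the mean reads of LepR-Cre− libraries. Background from genomic DNA or unspliced RNA may contribute but cannot be told apart from other sources: the share of reads on 757 olfactory, vomeronasal and trace amine receptor genes was 3.04 times as high in LepR-Cre+ libraries, yet 46.8 CPM (reads scaled to the library total, 95% Wilson interval 44.1 to 49.7) in LepR-Cre+ replicate 1 lay under the 49.8 (47.2 to 52.6) of LepR-Cre− replicate 2. The receptor genes include Olfr558, which the authors list as lower in LepR-Cre+ cells at P56 (log2 fold change -2.22). The share is therefore not a clean measure of background. LepR-Cre+ replicates 2 and 3 stood apart, with 129 and 211 CPM on the receptor genes. Of these genes 75.7% and 87.1% had a read in them, against 12.3% to 26.4% in every other P56 library. A difference of LepR-Cre+ cells themselves also stays open, as Gm10800 at P7 had a log2 fold change of 1.70 with overlapping groups.

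The mesothelial and the valve or tendon-like list passed downward at P56 with the preset correlation alone (adjusted p = 0.10 for each with an estimated one, with 0 of 9 and 1 of 13 members passing), and their members lower over the list alone did not follow each other across LepR-Cre− libraries. A lower share of fibroblasts in LepR-Cre− libraries would raise both alike only if mesothelial and valve or tendon-like cells entered in a fixed proportion. Only that case is argued against, and not a lower share from cells that differ between libraries. The median log2 ratio of replicate 1 over replicate 3 was -2.58 (range -2.62 to -2.22) over 5 mesothelial genes. It was 1.56 (range 1.06 to 2.11) over 6 valve or tendon-like genes, a gap of 4.14. Mesothelial cells sorted with LepR-Cre− cells are a candidate source of the first, as 8 of 9 mesothelial genes (of which Tbx18 and Rspo1 also stand in other lists) were highest in LepR-Cre− replicate 3, with 707 normalized reads of Msln, although the Col1a1-GFP gate would remove cells without GFP. For valve or tendon-like cells, 8 of 13 genes were highest in LepR-Cre− replicate 1, which leaves that source open. A difference between the sorted populations in these genes stays open, untested.

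Far fewer genes passed at P56 than at P7. Over the genes tested at both ages, larger spread between replicates is argued against. The median residual SD was 0.263 at P56 and 0.311 at P7, a ratio of 0.846. For the genes called at P7 it stays open, since their spread was not compared on its own. Among them Gdf10 and Esm1 had a larger SE at P56 than at P7, and Sfrp1 a smaller one. Lower depth is argued against by a ratio of mean reads of 0.955. Over the 120 genes called at P7 and tested at P56, 100 had the same sign and the median ratio of P56 to P7 log2 fold changes was 0.196 (quartiles 0.0589 to 0.377). Smaller differences between the populations at P56 may thus underlie the lower count, with the reservation that genes chosen for a large value at P7 shrink on remeasurement and that age goes with the table.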

How the results depend on the processing

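All of the added alternatives (edgeR with TMM, TPM, covariates, leaving out Gm models, further leave-one-out fits, the genes kept in them) were chosen after seeing the data. None of the alternatives for the authors' genes was fixed in advance. For the named genes only DESeq2, edgeR with RLE and the replicate block were. At P7 (148 genes, 106 higher and 42 lower), DESeq2 gave 628 (336 and 292), 1 fit of all 12 libraries 260 (155 and 105), the mitochondrial share as covariate 432 and the Ddx3y level 77 (65 and 12). Leaving out a library gave 29 to 113, over the genes of the full test, and 24 to 115 with the filter applied again, which drops genes expressed in the shortened group alone; edgeR, limma-voom, the filters and the pseudocounts gave counts within 1.5 times, though Hhip, Actg2 and Upk1b lost their calls at a pseudocount of 0.1 (adjusted p = 0.102, 0.0510 and 0.0940). Upk1b also lost it in edgeR (adjusted p = 0.0611 with RLE and 0.0619 with TMM) and Col4a3 in limma-voom (adjusted p = 0.0575). In 1 fit of all 12 libraries Nt5e, Cnn1, Ebf3 and Des lost theirs (adjusted p = 0.152, 0.0655, 0.0877 and 0.129). At P56 (3 genes), edgeR gave 1 with RLE and 1 with TMM (Wif1 lost, adjusted p = 0.0862 and 0.0810), limma-voom 0 (461 at an unadjusted p under 0.05, Tspan11 at an adjusted p of 0.0565 and Wif1 at 0.352), a TPM of at least 5 gave 0 (187 unadjusted), DESeq2 85 (39 higher and 46 lower), no filter 13 (7 and 6), 1 fit of 12 libraries 15 (7 and 8), limma on log2 TPM 46 (40 and 6, only 1 shared with the 3, as Tspan11 had 2.14 at an adjusted p of 0.0798 and Wif1 -3.56 at 0.0644), and the covariates gave 8 (mitochondrial share), 5 (genes with a read) and 20 (Ddx3y). Leaving out a library gave 0 to 5, and 0 to 7 with the filter applied again. For the difference between ages (19 genes, 0 higher), DESeq2 gave 137 (39 higher and 98 lower) and leaving out a library 8 to 20. Of the authors' genes (3 passing), edgeR passed 1 with RLE and 1 with TMM, limma-voom 0, DESeq2 51, no filter 13, a TPM of at least 5 gave 0, 1 fit of 12 libraries 13 and leaving out a library 0 to 5. Of the named genes 49 passed, against 25 on log2 TPM. Those lost on log2 TPM were Tspan11 and Wif1 at P56, Itgbl1 for the difference between ages (adjusted p = 0.228), and at P7 Hhip, Actg2, Matn4, Cnn1, Efemp1, Max, Nt5e, Diras2, Efhd1, Ebf3, Emilin2, Col4a4, Col4a3, Bmp3, Bmper, Wnt2, Colec12, Igf1, Twist2, Des and Upk1b (adjusted p from 0.0527 to 0.276). The cause of these shifts was not tested, but on simulated data without correlation between genes a larger share of DESeq2's calls was false.

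Lists passing at P7 (7) were 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 by fry and 4 to 9 without a library. On log2 TPM they were 5, with 0 higher and 5 lower, so that neither upward list passed. With the replicate number as a block they were 6, with 1 higher and 5 lower. At P56 (11) they were 0 (5 unadjusted), 1 and 6 to 14, and for the difference between ages (2) they were 0, 0 and 0 to 7, with 6 on log2 TPM. No list or named gene that passed changed direction without a library. No scaling moved the median log2 fold change of all genes by over 0.1.

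The samples share only a number, and nothing in the labels pairs them. As a hint from the data, libraries of the same number correlated at -0.0198, 0.224 and 0.217 at P7 and 0.335, 0.203 and 0.0398 at P56, after removal of group means, across genes. Sex-linked transcripts matched by number at P56, which leaves pairs possible without showing them. At P7 normalized reads of Ddx3y in LepR-Cre− and LepR-Cre+ libraries were 2640 and 293 for replicate 1. They were 313 and 5075 for replicate 3. Libraries of the same animals would match, so pairs from the same animals are argued against for those numbers. Other links between libraries of the same number could not be tested in this way. With the replicate number as a block, 435 genes passed at P7 (238 higher and 197 lower), 27 at P56 (15 and 12) and 87 for the difference between ages (22 and 65). All 27 at P56 were genes of the authors' lists with the authors' sign. If libraries of the same number are pairs at P56, the main test left that pairing unused. For the difference between ages 4 lists passed with the block. The cause of the higher counts was not tested. Age comparisons within a population and their alternatives were not run, since the tables were normalized separately. Genes with a mean under 1 TPM in both populations are outside the P7 table by its filter and were not analysed here at P7.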

Other observations

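Of 9 measured genes of the LepR+ stromal niche of bone marrow at P7, Ebf3, a transcription factor of marrow stroma, fell from 734 ± 94.8 to 279 ± 56.1 (log2 fold change -1.40, SE 0.22, adjusted p = 0.0320), 0 rose and 8 did not pass, with 2 up (Cxcl12 and Lepr) and 1 down adjusted over the list alone. Lepr carries the Cre driver by which cells were sorted, so its rise is not independent of the sort. The chemokine gene Cxcl12 had 5890 ± 1432 in LepR-Cre+ and 2544 ± 700.3 in LepR-Cre− libraries (log2 fold change 1.22, adjusted p = 0.0872), higher in 3 of 3 libraries. The list did not pass at P7 (adjusted p = 0.480) or at P56 (adjusted p = 0.893), where 0 of its 9 members passed. Ebf3 missed the threshold in 1 fit of all 12 libraries (adjusted p = 0.0877), and without LepR-Cre− replicate 1 (adjusted p = 0.205), LepR-Cre− replicate 2 (adjusted p = 0.0635), LepR-Cre− replicate 3 (adjusted p = 0.156), LepR-Cre+ replicate 1 (adjusted p = 0.160) or LepR-Cre+ replicate 2 (adjusted p = 0.0758).

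Sex-linked transcripts varied between libraries. At P56 both replicate 1 libraries had 4.56 (LepR-Cre−) and 1.2 (LepR-Cre+) normalized reads of Xist, the X-inactivation transcript, and 4755 and 4298 of the Y-linked Ddx3y, while the other libraries had 2649 to 5275 of Xist and 166 to 358 of Ddx3y. At P7 Xist and Ddx3y were 1079 and 2640, 99.4 and 5153, and 2399 and 313 in LepR-Cre− replicates 1 to 3, and 1012 and 293, 306 and 2966, and 226 and 5075 in LepR-Cre+ replicates 1 to 3.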
